A study of Homo sapiens with 18 samples.

How the data were processed

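Small RNA was sequenced from palatal gingiva of 9 healthy volunteers, each of whom gave a biopsy from an unwounded side of the palate (control, n = 9) and a biopsy from the other side, wounded 5 days before (prewound, n = 9). Per the labels' protocols, small RNA was enriched, 5 ng was ligated to Ion adapters, and the cDNA was amplified by PCR with barcoded primers. Both biopsies of a volunteer were taken in the same appointment, and the replicate number is the volunteer. The deposited data are 3 tables, of annotated small RNA genes (7768 features), of mature miRNA arms (2104 features) and of annotated genes together with unannotated loci (8988 features, of which 1220 are unannotated). Coordinates are those of the tables, in genome build hg19 per the submitters' processing notes. The aligner, the counting rule and the normalization are not given in the sources used here.

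The deposited values are in log2 units, named as normalized reads per the file headers. Within a feature, 2 to the power of the values became whole numbers after multiplication by 1 constant, which recovered read numbers for 3278 of 3280 varying features in the gene table, 976 of 977 in the arm table and 3015 of 3016 in the table with unannotated loci. The recovery was tested on simulated data, where it was right for 744 of 744 features of up to 100000 reads and for 85 of 256 above, with 0 wrong. The deposited log2 values therefore carry reads with 0 set to 1, less a constant for each feature, and no scaling between libraries was visible in them. For mir-203, mir-205 and miR-205-5p the constant was not found, so their fold changes are usable, their read levels are lower bounds, and they were left out of totals and shares. Some copies of the same mature sequence hold nearly equal reads and others differ, so totals can count some reads more than once. Counts of hairpins and arms can likewise count 1 sequence more than once. The 4 columns without a described sample, in 2 of the tables, were not used.

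The test planned before the data were examined took deposited log2 values as they stood. Because the values proved to be unscaled, read numbers were instead divided by a library factor, the mean log2 ratio to the average library after trimming a fraction of 0.3 at each end, over features with at least 10 reads on average. Features with at least 5 reads in at least 9 of the 18 libraries were kept. Values of log2(scaled reads + 1) were compared with limma 3.58.1 (lmFit, eBayes with a mean-variance trend, 2-sided) in R 4.3.3, with Benjamini-Hochberg adjustment within each table and a threshold of 0.05. Errors beside log2 fold changes are limma standard errors, and errors beside levels are SD. Fold changes are prewound over control. Each table was scaled by its own features, and unannotated loci were adjusted among themselves.

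The volunteers pair the samples per the labels. Deviations from the group mean of samples from the same volunteer had a median correlation of 0.215 over genes (range −0.123 to 0.526) and 0.138 over mature arms. Since neither the labels nor the series text states a paired test, the volunteer entered as a block only in an alternative fit.

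The 18 lists of miRNAs were fixed beforehand. They cover epithelial, leukocyte, myeloid, lymphoid, red cell and platelet, smooth muscle and endothelial, skeletal muscle, mesenchymal and fibrotic, neural and melanocyte miRNAs, the imprinted chromosome 14 cluster, the miR-17-92 cluster with its paralogs, miRNAs reported in wound repair, and the let-7, miR-99 and miR-100, miR-15, miR-16 and miR-195, miR-34 and miR-449, and miR-30 families. Each was tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, over lists with at least 3 members tested. Shares of reads by RNA class were compared by 2-sided exact permutation tests over all 48620 arrangements, whose smallest p is 4.1e-05, and by exact sign-flip tests over the 9 volunteers, whose smallest p is 0.0039. The named genes are the 10 with the largest change in each direction past the threshold whose direction was shared by at least 7 volunteers, or all if fewer passed. To these were added the 5 largest each way for mature arms and for unannotated loci, each member of the wound repair, leukocyte and epithelial lists past the threshold, and miR-21, miR-223, miR-31, miR-203, miR-205 and miR-146a whatever their result. Other members of lists and other arms named in the text were chosen after their values were seen.

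In simulated libraries with the real means and depths, the fit recovered 69.2% of 2-fold changes and 100% of 4-fold changes among 1559 genes, 89.2% and 100% among 510 arms, and 62.5% and 100% among 539 unannotated loci. For 1.5-fold changes the shares were 16.4%, 68.7% and 23.1%. The share of calls that were false was 4.69%, 1.16% and 4.96%, and 0 features were called when no change was simulated. Features were simulated independently of each other, so these shares do not cover false calls from variation that features share. In the real data, 1 other grouping of the libraries called 288 genes. Alternatives were other pseudocounts, filters and scalings, values without scaling, a robust variance, voom on the recovered reads, the volunteer as a block, miRNA genes tested alone, and omission of each volunteer. Reads without molecular identifiers are not independent molecules, so depth gives only the counting error.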

Results

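The series profiled small RNAs of human palatal gingiva 5 days after wounding, in 9 prewound biopsies and 9 control biopsies from the opposite side of the same volunteers. Reads assigned to annotated small RNA genes totalled 3.14 ± 1.54 M reads per control library and 3.81 ± 0.895 M per prewound library (SD, n = 9 each), from 1.40 M in control replicate 3 to 6.37 M in control replicate 7. Mature miRNA arms held 0.581 to 3.48 M reads per library, and the table with unannotated loci 1.09 to 4.45 M. The log2 totals of annotated genes differed by 0.38 between the groups, within the spread between libraries (2-sided exact permutation p = 0.160, n = 9 per group).

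miRNA hairpins took most of the reads, 52.4 ± 13.4% in control and 50.3 ± 11.7% in prewound libraries (SD, n = 9 each). snoRNAs, which guide chemical modification of ribosomal RNA, took 34.6 ± 12.6% and 35.9 ± 12.3%. tRNA reads made up 11.3 ± 4.20% and 12.2 ± 2.56%, snRNA reads 1.37 ± 0.545% and 1.31 ± 0.270%, and scRNA reads 0.267 ± 0.0962% and 0.276 ± 0.0445%. Of the 9 classes, pseudogene classes included, 0 differed in share past the threshold and 0 at an unadjusted p under 0.05, both in the 2-sided exact permutation test (smallest p = 0.159) and in the exact sign-flip test over volunteers (smallest p = 0.207). The share of miRNA reads ranged from 31.6% in prewound replicate 2 to 76.8% in control replicate 8.

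The first comparison asks which small RNA genes differ between healing and unwounded gingiva. mir-21, a hairpin known to be induced in injured and inflamed tissue, was 4.73-fold higher in prewound tissue (log2 2.24 ± 0.20, n = 9 per group), and rose from 38303 ± 7816 to 183834 ± 48105 scaled reads, higher in 9 of 9 volunteers. mir-223, abundant in neutrophils and other myeloid cells, was 9.46-fold higher (3.24 ± 0.53, higher in 8 of 9), and mir-142, expressed in blood-forming lineages, was 4.46-fold higher (2.16 ± 0.32, higher in 9 of 9). The neighbours mir-132 and mir-212 on chromosome 17, mir-132 being reported to dampen inflammation and promote keratinocyte growth in skin wounds, were 2.66-fold and 3.38-fold higher. In the other direction, mir-675, which is cut from the imprinted H19 RNA, was 2.42-fold lower, and let-7c and mir-99a, whose hairpins lie within 1 kb of each other on chromosome 21, were 1.93-fold and 1.90-fold lower.

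Of 1544 genes tested with limma, 32 passed the threshold, 27 higher and 5 lower in prewound tissue, and 189 had an unadjusted p under 0.05. The higher genes were 18 miRNA hairpins, 5 tRNAs, 2 snoRNAs and 2 snRNAs, and the 5 lower genes were all miRNA hairpins. Without scaling, as the test was planned before the data were examined, the median gene was raised by 0.39 log2 units, and 58 genes passed, all 58 higher. In that setting the 5 lower genes still had negative fold changes but lost their calls (adjusted p = 0.183 to 0.421).

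The largest rises after mir-223, mir-21 and mir-142 were those of mir-431 (log2 1.87 ± 0.29), mir-212 (1.76 ± 0.28), SNORD114-10 (1.62 ± 0.36), mir-503 (1.61 ± 0.25), SNORD114-13 (1.61 ± 0.39), mir-665 (1.57 ± 0.32) and mir-146b (2.83-fold). mir-431 and mir-665 are hairpins of the imprinted region of chromosome 14, at 101347344 to 101347457 and 101341370 to 101341441, and both SNORD114 genes are snoRNAs of the same region, near 101433389 and 101436216. mir-21 lies at 57918627 to 57918698 of chromosome 17, mir-142 at 56408593 to 56408679 of the same chromosome, and mir-223 at 65238712 to 65238821 of chromosome X. mir-146b, which restrains signalling from Toll-like receptors, was at 852 ± 233 scaled reads in control and 2448 ± 852 in prewound tissue (adjusted p = 0.000474, limma, higher in 9 of 9 volunteers). mir-503, of the miR-15/16 family that slows the cell cycle, went from 69.2 ± 23.3 to 220 ± 82.0 scaled reads (adjusted p = 0.000627, limma, 9 of 9). mir-132 (1.41 ± 0.25) and mir-511-2, a hairpin within a macrophage receptor gene (1.13 ± 0.29), entered as members of the wound repair and leukocyte lists. Also higher, and outside the rule for named genes, were mir-7-2 (1.06 ± 0.25), mir-135b (1.02 ± 0.26), the histone-processing RNU7-1 (0.96 ± 0.24) and RNU5E-6P (1.03 ± 0.26), chosen after their values were seen.

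The 5 lower genes were mir-675 (−1.28 ± 0.30), mir-138-1 (−1.05 ± 0.27), let-7c (−0.95 ± 0.22), mir-99a (−0.93 ± 0.23) and mir-149 (−0.85 ± 0.18). mir-675 fell from 168 ± 84.6 to 67.3 ± 30.2 scaled reads and was lower in 9 of 9 volunteers, as were let-7c, mir-99a and mir-149. The drop of mir-99a, whose family restrains growth signalling through mTOR, was from 39113 ± 13614 to 20132 ± 5330.5 scaled reads. Of the hairpins fixed beforehand, mir-31, induced in keratinocytes of healing skin, had 1.06 ± 0.36 (adjusted p = 0.149, limma, higher in 8 of 9 volunteers). The epithelial mir-203 and mir-205 had −0.48 ± 0.19 (adjusted p = 0.251) and −0.27 ± 0.21 (0.661), and mir-146a had −0.02 ± 0.30 (0.999), in contrast to its relative mir-146b. Without scaling, the log2 fold changes of mir-205 and mir-146a were 0.12 and 0.36. With the volunteer as a block, mir-138-1 and mir-135b no longer passed (adjusted p = 0.0833 and 0.0706). Of the 17 named genes that passed, 8 did so whichever volunteer was left out, namely mir-223, mir-21, mir-142, mir-431, mir-212, mir-503, mir-146b and mir-132, while each of the other 9 lost its call without replicate 11 and all but mir-665 without others too, with highest adjusted p from 0.0638 for mir-149 to 0.190 for mir-138-1.

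Among 395 miRNA hairpins tested, 23 passed over all genes, 18 higher and 5 lower. Adjusted over miRNA genes alone the numbers were 25 higher and 10 lower, and when miRNA genes were also scaled and fitted alone, 55 were higher and 54 lower, with all 23 among them. The median standard error was 0.202 in that fit against 0.249 in the fit of all genes. With copies of a miRNA summed, 20 of 359 miRNAs passed over all genes, 16 higher and 4 lower. Leaving out replicates 2, 3, 4 or 11 reduced the count over all genes from 32 to 18, 12, 13 or 10, and the count of miRNA genes from 23 to 15, 12, 10 or 9.

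The second comparison asks the same of mature miRNA arms, the strands loaded to silence target mRNAs. miR-21-5p was 4.78-fold higher in prewound tissue (log2 2.26 ± 0.14, n = 9 per group, higher in 9 of 9 volunteers) and went from 37588 ± 5801 to 182449 ± 46564 scaled reads. Its partner strand miR-21-3p was 7.19-fold higher (2.85 ± 0.26), and miR-223-3p 9.51-fold higher (3.25 ± 0.47). The largest falls were those of miR-124-3p, a neuronal miRNA whose copies fell by 1.51 to 1.58 log2 units from about 20 scaled reads, miR-675-5p (−1.40 ± 0.35) and miR-375, known from endocrine and secretory epithelium (−1.36 ± 0.49). let-7c, a family that holds cells in a differentiated state, was lower in 9 of 9 volunteers (−0.93 ± 0.16).

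Of 505 arms tested, 123 passed with limma, 63 higher and 60 lower, and 189 had an unadjusted p under 0.05. Without scaling, where the median arm moved up by 0.37 log2 units, 54 passed as higher and 1 as lower, and 57 of the 60 lower arms kept a negative fold change. The other arms with the largest rises were miR-142-3p (2.28 ± 0.25), miR-223-5p (2.27 ± 0.38) and miR-431-5p (2.27 ± 0.34). miR-223-3p had 2546 ± 1897 scaled reads in control and 40198 ± 66451 in prewound tissue, or 18287 ± 10419 there without prewound replicate 3. miR-142-3p had 881 ± 259 and 4646 ± 2353. The arm miR-375 went from 483 ± 610 (312 ± 355 without control replicate 2) to 118 ± 64.9 scaled reads, and its call (adjusted p = 0.0454, limma) was lost without replicate 2, 3, 6, 7, 8 or 11, with adjusted p up to 0.125. Of the 10 named arms, 8 passed whichever volunteer was left out, and 1 copy of miR-124-3p lost its call without replicate 4, 6 or 11, with adjusted p up to 0.0557. Leaving out replicate 11 reduced the count of arms from 123 to 80.

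**Figure D1:**
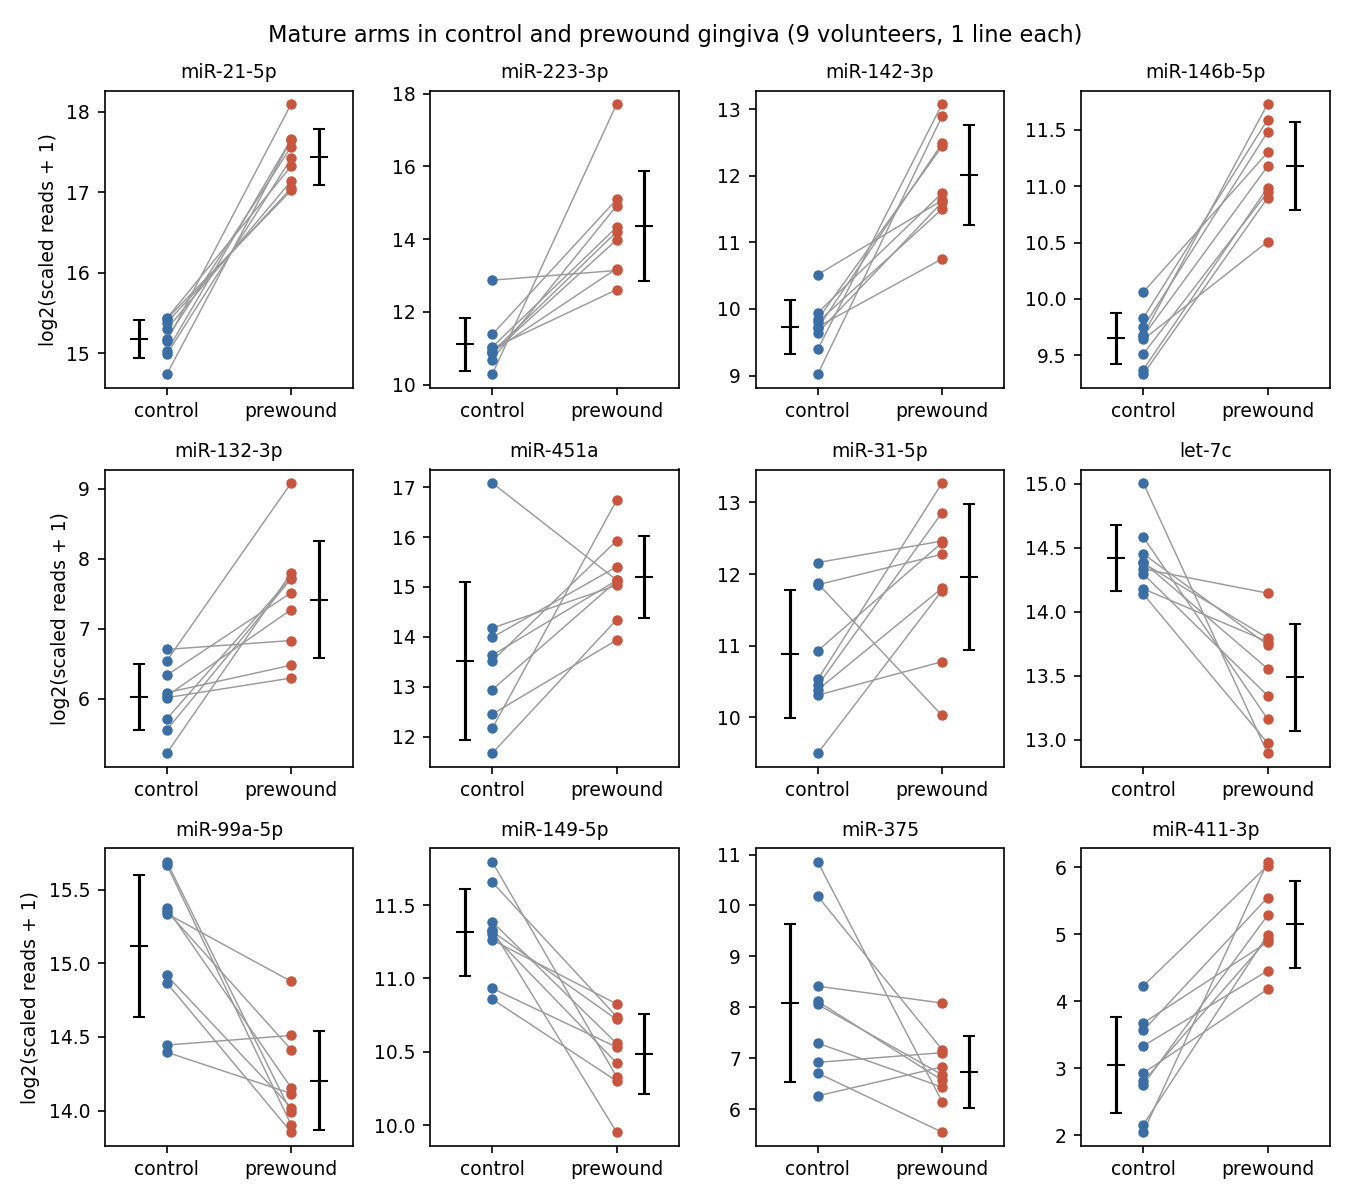
Log2 scaled reads of 12 mature miRNA arms in control and prewound gingiva, with a line for each of 9 volunteers and the mean ± SD of each group beside it. miR-21-5p, miR-142-3p and miR-223-3p were higher on the prewound side in 9 of 9 volunteers, and let-7c was lower in 9 of 9.

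**Figure D2:**
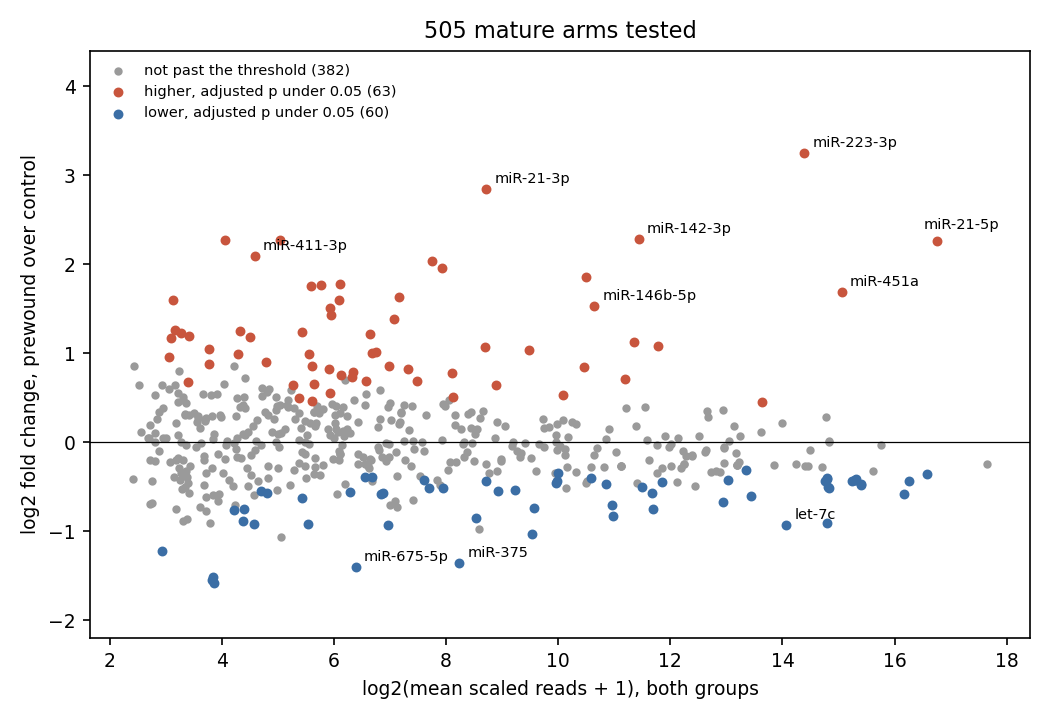
Mean log2 level of each of 505 mature arms against its log2 fold change, prewound over control. Coloured points are the 63 arms that were higher and the 60 that were lower past the threshold, and the level of miR-205-5p is a lower bound.

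The lists fixed beforehand group these miRNAs by cell type and family. Myeloid miRNAs rose together, with 4 of 7 hairpins higher over all genes and 7 of 7 when adjusted over the list alone (median log2 1.13, camera adjusted p = 7.0e-13). It was the only list that also passed with an estimated correlation (adjusted p = 0.0118). Adjusted p with an estimated correlation depended on the scaling, and was lower for every list of hairpins with scaling on miRNA features alone. In that setting the leukocyte, lymphoid, wound repair, and miR-99 and miR-100 lists had adjusted p = 0.0675 each. The myeloid list was still the only one to pass there (adjusted p = 0.000702). Its mature arms were higher in 7 of 8 cases, 8 of 8 adjusted over the list alone, although with an estimated correlation the list of arms did not pass (adjusted p = 0.0761). They include miR-223-3p, miR-142-3p, miR-146b-5p (1.53 ± 0.15) and miR-155-5p (0.82 ± 0.18), a regulator of activated macrophages and lymphocytes. The wider leukocyte list, which holds all 7 myeloid hairpins, had 4 of 16 hairpins higher and 12 not past the test, 8 higher adjusted over the list alone and 7 over all genes with the volunteer as a block (adjusted p = 7.4e-05), but not with an estimated correlation (adjusted p = 0.452). Among its 22 arms 9 were higher and miR-181a-2-3p was lower (−0.93 ± 0.21), with 11 and 2 under the block. The lymphoid list of 3 hairpins had 0 past the test over all genes and 2 higher either adjusted over the list alone or with the volunteer as a block (adjusted p = 0.00296, and adjusted p = 0.30 with an estimated correlation). The lymphocyte arm miR-150-5p was higher by 1.12 ± 0.28 and in 9 of 9 volunteers.

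Arms of red cell miRNAs were higher beside those of leukocytes. miR-451a, the main miRNA of red cells, was higher by 1.68 ± 0.50 (adjusted p = 0.0182, limma, higher in 8 of 9 volunteers), miR-144-3p by 1.85 ± 0.59, miR-144-5p by 1.96 ± 0.54 and miR-486-5p by 1.76 ± 0.50. Control replicate 8 stood apart in this group, with 17.08 log2 scaled reads of miR-451a against 14.18 in the next control library, and in that volunteer alone the mean log2 change of the 4 arms was below 0, at −2.14. Of the 12 red cell and platelet arms, 8 stand in another list too. These 4 of 12 arms passed, while 0 of 8 hairpins passed over all genes and 2 adjusted over the list alone. As a list the hairpins did not pass (adjusted p = 0.164), except when replicate 8 was left out (adjusted p = 0.00839, and adjusted p = 0.303 with an estimated correlation), and neither did the arms (adjusted p = 0.0918).

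In the list of miRNAs reported in wound repair, 5 of 21 hairpins were higher, 1 lower and 15 not past the test, and 7 were higher and 3 lower adjusted over the list alone. mir-21, mir-212, mir-503, mir-146b and mir-132 were the higher ones and mir-99a the lower. The list passed upward (adjusted p = 0.00646, and adjusted p = 0.503 with an estimated correlation) although its median was near 0, at −0.0027 against a mean of 0.37, and the sign of that median turned without scaling (0.39), with quantile scaling (0.14) and with scaling on miRNA features alone (0.018). Among its 31 arms, 10 were higher, 4 lower and 17 not past the test. miR-31-5p and miR-31-3p, both 1.08 higher on the log2 scale, passed as arms (adjusted p = 0.0454 for each, limma), and miR-203 was lower (−0.44 ± 0.14, adjusted p = 0.0263).

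Hairpins of the imprinted chromosome 14 cluster, which is expressed in embryonic, neural and mesenchymal tissue, passed upward as a list of 35 (median 0.35, adjusted p = 3.2e-05, but adjusted p = 0.503 with an estimated correlation). mir-431 and mir-376a-2 were higher over all genes and 33 did not pass, and 2 were higher adjusted over the list alone. Of its 51 arms 12 were higher and 0 lower, both over all arms and adjusted over the list alone. miR-411-3p (2.10 ± 0.31), miR-431-5p, both copies of miR-376a-3p (1.43 ± 0.22 for the copy that moved less) and miR-323a-3p (1.25 ± 0.31) were among them. The miR-17-92 cluster with its paralogs, a driver of cell division, had a median near 0, at 0.057 against a mean of 0.29. Against miRNA genes alone it did not pass (camera adjusted p = 0.0754). Against all genes it passed upward with 0 of 15 hairpins past the test and 1 adjusted over the list alone (adjusted p = 0.0278, and adjusted p = 0.573 with an estimated correlation). Leaving out replicates 6 or 9 ended that call (adjusted p = 0.127 and 0.0765). Its arms miR-18a-5p (0.84 ± 0.21), miR-20b-5p (1.00 ± 0.29), miR-106a-5p (0.82 ± 0.23) and miR-19a-3p (0.46 ± 0.11) were higher, and the other 18 of 22 did not pass.

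The let-7 list passed downward, with let-7c lower and 11 of 12 hairpins not past the test, also 1 lower adjusted over the list alone (adjusted p = 0.00289, and adjusted p = 0.503 with an estimated correlation). Its median of −0.29 was 0.095 without scaling. Of 22 let-7 arms 7 were lower, among them let-7b-5p (−0.44 ± 0.13), but 3 with the volunteer as a block, where let-7c and let-7b-5p were among those that passed. The 7 include the copies of let-7a-5p, which hold nearly equal reads (46095 to 46464 scaled reads in control) and are not independent. The miR-99 and miR-100 list had mir-99a of 3 hairpins lower, and 2 adjusted over the list alone (adjusted p = 0.0102, and adjusted p = 0.30 with an estimated correlation), and its arms miR-99a-5p (−0.91 ± 0.18) and miR-100-5p (−0.61 ± 0.18) were lower. Epithelial miRNAs passed downward as a list with 0 of 14 hairpins past the test, also 0 adjusted over the list alone (adjusted p = 0.00724, and adjusted p = 0.503 with an estimated correlation), and the median of −0.25 was 0.14 without scaling. The call ended without replicate 7 (adjusted p = 0.056). As arms, miR-200b-3p (−0.51 ± 0.15) and miR-429 (−0.46 ± 0.17), which maintain the epithelial state by repressing ZEB factors, were lower with miR-203 and miR-375, and 16 of 20 did not pass. miR-205-5p, a marker of basal keratinocytes, had −0.25 ± 0.16 (adjusted p = 0.270).

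Melanocyte miRNAs passed downward with 0 of 8 hairpins past the test, 0 adjusted over the list alone (adjusted p = 0.00742, and adjusted p = 0.503 with an estimated correlation), and the arm miR-204-5p was lower (−0.71 ± 0.23), 1 of 9 arms against 2 with the volunteer as a block. Smooth muscle and endothelial miRNAs passed downward with 0 of 8 hairpins past the test and 3 lower adjusted over the list alone (adjusted p = 0.0112, and adjusted p = 0.503 with an estimated correlation), except without replicate 8 (adjusted p = 0.0519). The arms miR-23b-3p (−0.58 ± 0.14), miR-27b-3p (−0.44 ± 0.13) and both copies of miR-24-3p (−0.48 ± 0.13) were lower. Among the hairpins too, mir-23b, mir-24 and mir-27b fell most. The other members were mir-126 at 0.15 ± 0.23, mir-139 at −0.06 ± 0.23, mir-143 at −0.10 ± 0.39 and mir-145 at −0.34 ± 0.35. The list therefore did not fall as a whole. The lists that did not pass were mesenchymal and fibrotic miRNAs (adjusted p = 0.767), where mir-21 rose and 19 of 20 hairpins did not pass and the test pointed up against a median of −0.096 (0.29 without scaling), and neural miRNAs (0.228), where mir-7-2 was higher and mir-138-1 lower. Nor did miR-15, miR-16 and miR-195 (0.767), where mir-503 rose and the test pointed down against a mean of 0.019, miR-34 and miR-449 (0.464), miR-30 (0.0927) or skeletal muscle (0.0741, but 0.0395 with the volunteer as a block, and 0.484 with the block and an estimated correlation). With miRNA features alone for scaling, miR-30 and skeletal muscle passed downward (adjusted p = 0.0239 and 0.0394, and 0.274 and 0.359 with an estimated correlation), although the median of miR-30, −0.27, was 0.12 without scaling. Adjusted over the list alone, mir-21, mir-503 and 3 neural hairpins were higher and 2 of the miR-15, miR-16 and miR-195 family and 4 neural hairpins were lower. In all, 11 of 18 lists passed, 6 upward and 5 downward, against a median of 5 lists in other splits of the libraries (3 in splits that part every pair). Against miRNA genes alone 6 passed, namely myeloid, leukocyte, lymphoid, chromosome 14 cluster, wound repair and let-7 miRNAs. The epithelial, melanocyte, smooth muscle and endothelial, and miR-99 and miR-100 lists did not (camera adjusted p = 0.0736 for each), nor did the miR-17-92 cluster (0.0754). With fry, which tests whether the members of a list move on balance in 1 direction, 4 of the 11 lists passed, namely myeloid (adjusted p = 0.000116), lymphoid (0.0291), miR-99 and miR-100 (0.0291) and leukocyte miRNAs (0.0411). The other 7 had fry adjusted p from 0.0755 for wound repair to 0.373 for the miR-17-92 cluster, with 0.277 for the chromosome 14 cluster. On arms, 6 lists passed with camera, and these 6 and 8 more with fry, but 0 with an estimated correlation (lowest adjusted p = 0.0761).

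**Figure D3:**
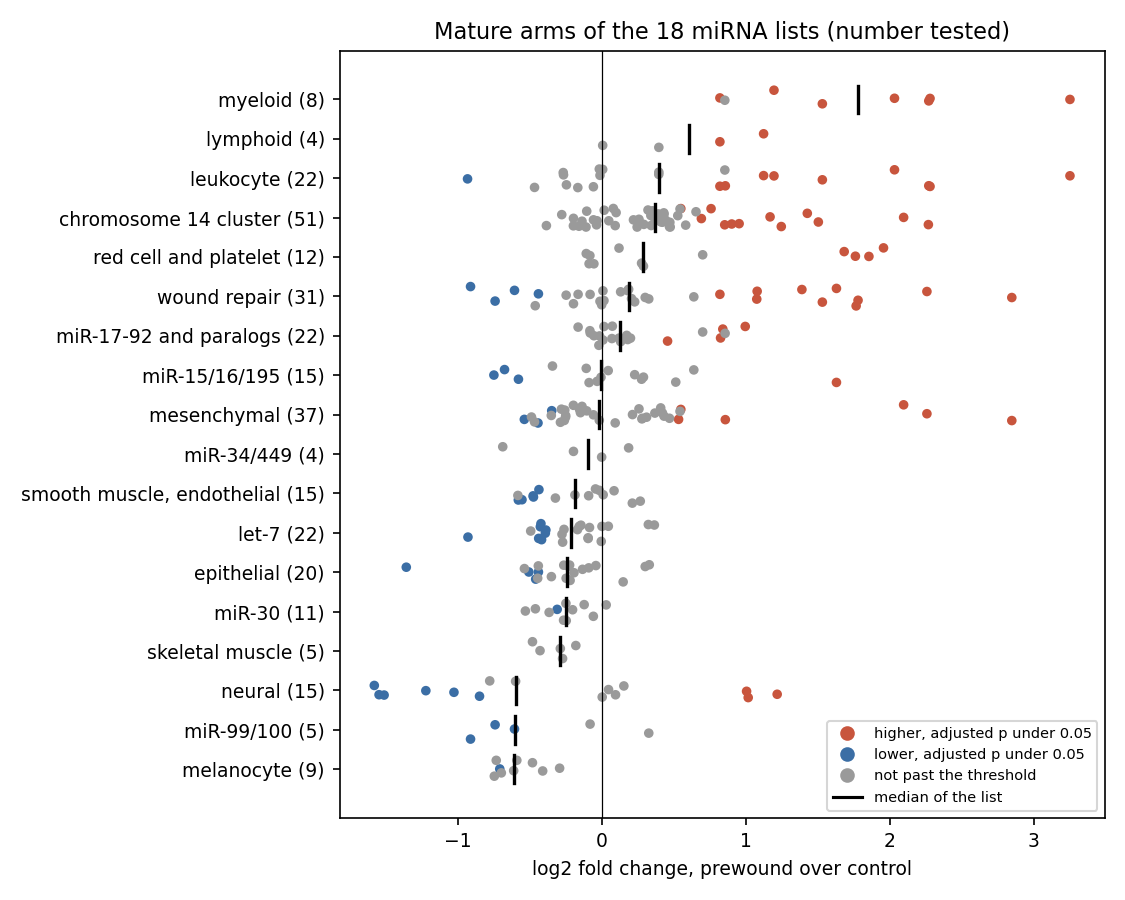
Log2 fold changes, prewound over control, of the mature arms in each of 18 lists, each point an arm and each bar the median of its list. Myeloid arms lie highest, with a median of 1.78, and the miR-99 and miR-100 and melanocyte arms have medians of −0.61 and −0.61.

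The third comparison covers loci that the deposited table lists without an annotated gene. The strongest rise was that of NEWGENE72, a 61 nt locus at 62804227 to 62804287 of chromosome 5, which was 7.04-fold higher in prewound tissue (log2 2.82 ± 0.55, n = 9 per group, 9 of 9 volunteers). The strongest falls came from 4 loci of 216 to 584 nt, typed as tRNA in the table, on the minus strand of chromosome 12 between 53068506 and 53072545. Of these, NEWGENE1126 was 6.50-fold lower (−2.70 ± 0.40), NEWGENE1127 5.63-fold lower (−2.49 ± 0.36), NEWGENE1130 3.72-fold lower (−1.90 ± 0.35) and NEWGENE1132 3.27-fold lower (−1.71 ± 0.38). The genes around these loci are not given in the sources used here. Whether the 4 neighbouring loci of chromosome 12 are separate RNAs was not tested, so their falls cannot be taken as independent.

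Of 485 unannotated loci tested, 30 passed with limma, 21 higher and 9 lower, and 28 higher and 4 lower without scaling, where the median locus moved up by 0.41 log2 units. By the type in the table, 11 loci of unknown type, 7 typed as miRNA and 3 as tRNA were higher, and 2, 3 and 4 were lower. NEWGENE678 on chromosome 1 (1.97 ± 0.27), NEWGENE633 on chromosome 9 (1.84 ± 0.39), NEWGENE401 on chromosome 17 (1.68 ± 0.32) and NEWGENE53 on chromosome 8 (1.62 ± 0.35) followed among the higher ones, and all had fewer than 10 scaled reads on average in control tissue. NEWGENE678 went from 9.58 ± 3.04 to 39.9 ± 9.46 scaled reads (adjusted p = 3.4e-05, limma). NEWGENE62 on chromosome 3 was lower (−1.37 ± 0.42, adjusted p = 0.0480, limma), but of the 9 omissions of a volunteer it passed only in that of replicate 7, with adjusted p up to 0.177. The other 9 named loci passed whichever volunteer was left out, and the count fell to 17 without replicate 11 and to 19 without replicate 2 or replicate 4.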

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

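Tests chosen only after the result was seen were those for blood, for leukocytes of all kinds, for mesenchymal cells and for a true rise of all small RNAs, and the search for libraries that stand apart in arms and genes outside the rule for named genes. In 19 of 224 sets of 9 libraries (8.48%), the highest or lowest library lay farther from its nearest neighbour than the spread of the set allows at a 1 in 20 chance, and chance flags about 1 in 20 sets. Control replicate 8 was the library in 7 of these 19, of which 6 were leukocyte or red cell miRNAs. It had 13.77 log2 scaled reads of mir-223 (next control library 11.60), 12.04 of mir-142 (10.67) and 12.87 of the arm miR-223-3p (11.38). It also had 17.08 of the red cell arm miR-451a (14.18), 12.86 of miR-144-3p (9.63), 9.93 of miR-144-5p (6.82) and 6.36 of miR-20b-5p (5.02), a paralog of the miR-17-92 cluster. Scaling adds to its hairpin levels. Its log2 factor was 0.318 over all annotated genes against 1.07 over miRNA features. Among arms, which were scaled by miRNAs, miR-142-3p of control replicate 8 was at 10.52 (next 9.94) and was not flagged. Prewound replicate 3 had 17.72 of miR-223-3p (next prewound library 15.09).

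Other libraries stood apart in single miRNAs. Prewound replicate 7 had 8.45 log2 scaled reads of mir-135b (next 9.51), 8.612 of its arm miR-135b-5p (9.76) and 6.062 of miR-125b-2-3p (5.18). miR-125b-2-3p was at 4.898 in control replicate 3 (next 5.57), and 1 copy of miR-376a-3p at 4.324 in control replicate 7 (4.82). miR-150-5p was at 11.35 in control replicate 4 (next 10.63) and at 13.54 in prewound replicate 9 (11.99). miR-429 was at 9.296 in control replicate 4 (next 10.03). miR-411-5p was lowest in both libraries of replicate 2, at 3.933 in control (next 5.15) and 4.822 in prewound tissue (5.77). The scRNA share of control replicate 2 was 0.4937%, against 0.282% in the next control library.

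Myeloid miRNAs were higher in prewound tissue. More myeloid cells in the healing tissue may account for it. The paired changes of miR-223-3p and miR-142-3p went together across the 9 volunteers (Pearson's r = 0.81, exact permutation p = 0.00388, adjusted p = 0.0155 over 4 relations). Spearman's rho was 0.82 (permutation p = 0.0108), and r was 0.77 without the 2 volunteers farthest from the median. miR-21-5p, outside the myeloid list, followed miR-223-3p with r = 0.55 (exact permutation p = 0.123), but 0.74 without those 2 volunteers. For miR-150-5p r was 0.43 (exact permutation p = 0.230). As mir-142 is expressed in blood-forming lineages, blood, a rise of all leukocytes or other sources of myeloid RNA would give the same relation. The relation therefore cannot single out myeloid cells. Blood left in the biopsy stays open, because myeloid arms differed from red cell arms by a mean paired change of −0.034 log2 units (SD 1.52, exact sign-flip p = 0.965), and the changes of miR-223-3p and miR-451a had r = 0.43 (exact permutation p = 0.236, n = 9), which depends on single volunteers, as r was −0.030 without replicate 8 (exact permutation p = 0.934, n = 8) and 0.76 without replicate 3 (exact permutation p = 0.0351, n = 8). The mean difference was −0.45 without replicate 8, in whose own tissue red cell arms changed by −2.14 log2 units and myeloid arms by 1.16. A rise of all leukocytes by 1 factor stays open too, for although the 7 myeloid arms outside the lymphoid list rose by 1.41 log2 units more than the 3 lymphocyte arms (SD 0.768, 9 of 9 volunteers, exact sign-flip p = 0.0039), the lymphocyte arms started from a median of 1471 scaled reads in control tissue against 77.4, and part of that baseline may come from other cells. These medians depend on the arms counted. Among myeloid arms miR-223-3p started from 2546 and miR-223-5p from 8.93 scaled reads, and among lymphocyte arms miR-342-3p from 2569 and miR-342-5p from 42.8.

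miRNAs of the imprinted chromosome 14 cluster were higher in prewound tissue as a list. Low reads alone did not go with a rise, since 10000 random sets of miRNA genes matched on level had a median of −0.036. The median of its 35 hairpins lay at percentile 99.88 of these sets. Reads shared between copies were not needed for the rise, as the 28 hairpins without a copy had a median of 0.34 (percentile 99.88). Both percentiles are too high, because random members were drawn 1 by 1 while the cluster's hairpins vary together (estimated correlation 0.66). They cannot tell whether the rise exceeds chance. The 13 mesenchymal hairpins outside the cluster did not rise with it. Their median was −0.23 (bootstrap SE 0.091), with 3 above 0, against 0.35 for the cluster. That error is too small, because it takes hairpins as independent. Some are copies of 1 miRNA, and the members of the mesenchymal list vary together (estimated correlation 0.52). More mesenchymal cells as a source therefore stay open. A change of the locus within some cells, which may be the source, was not tested, and the list's call was lost with an estimated correlation.

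Calls were nearly all higher when the reads were tested without scaling. More reads per prewound library may be the source, since the median miRNA gene, 0.31 log2 units higher without scaling, was at −0.086 when scaled by the other RNA classes. A true rise of all small RNAs per cell cannot be told apart from deeper sequencing, as no added standard is in the tables, and log2 totals differed at 2-sided exact permutation p = 0.160 (n = 9 per group).

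The counts were compared with those of 100 splits of the libraries into 9 and 9, the real one included. Over all splits, few counts were as large as the real one for genes (32, highest other split 288, with 2 of 100 as large) and miRNA genes (23, highest other 71, with 2 as large). Chance was not excluded there, since another grouping gave a larger count. No other split drawn reached the counts of arms (123, highest other 78, with 1 as large) and unannotated loci (30, highest other 18, with 1 as large). Chance could not be excluded for gene lists either (11, highest other 16, with 7 as large), where the median of the other splits was 5 lists against 0 genes, miRNA genes, arms and loci. The split with 288 genes, several times the real count, points to a structure of the samples in the gene table, whose nature was not tested, and the same split called 0 arms and 18 unannotated loci. Among 100 splits that part every pair, as the real one does, no other split reached the counts of genes (highest other 2), miRNA genes (highest other 1), arms (highest other 49) or unannotated loci (highest other 9). Chance alone is therefore an unlikely source of these counts, although 100 splits cannot give a share under 1 in 100. For gene lists 4 splits were as large (highest other 12, median 3).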

How the results depend on the processing

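Scaling by a trimmed mean, used for the main result, was chosen after seeing the data, and values without scaling are those of the plan. Other choices made after seeing the data were factors from miRNA features alone, voom, miRNA genes fitted alone or adjusted alone with the block, lists with the block and an estimated correlation, lists on arms, and omission of volunteers for lists and class shares. The planned count-model tests were not run, because read numbers were recovered rather than deposited, and voom was used in their place. Other pseudocounts, quantile scaling, factors from miRNA features, voom and a robust variance kept the counts of genes, arms and unannotated loci within 1.5 times. With no filter 20 genes and 15 miRNA genes passed, and with a filter of 50 reads 21 genes and 6 unannotated loci; the number of features tested changed with the filter. Without scaling 58 genes and 55 arms passed, and with the volunteer as a block as well 77 genes and 46 miRNA genes. miRNA genes adjusted alone gave 35 calls, 61 with the block, and 109 when also scaled and fitted alone. With the volunteer as a block on scaled reads the counts were 38 genes, 28 miRNA genes, 139 arms, 35 unannotated loci, 12 lists and 0 class shares; the block ended the calls of mir-138-1 (adjusted p = 0.0833) and mir-135b (adjusted p = 0.0706), added skeletal muscle among lists (adjusted p = 0.0395, but 0.484 with an estimated correlation) and the arm miR-342-3p (adjusted p = 0.0212), reduced the lower let-7 arms from 7 to 3, and changed no other call of a gene, arm, locus or list that the text names. Of 11 lists, 1 passed with an estimated correlation, 1 with the block and an estimated correlation, and 6 against miRNA genes; on arms 6 lists passed, and 0 with an estimated correlation (lowest adjusted p = 0.0761). Without scaling mir-205 was at 0.12 and mir-146a at 0.36, and the same with the block; the cause was not tested beyond the depth of the libraries.

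Leaving out each volunteer gave 10 to 41 genes, 9 to 26 miRNA genes, 80 to 127 arms, 17 to 36 unannotated loci, 10 to 13 lists and 0 class shares. The lowest counts came without replicate 11 (10 genes, 9 miRNA genes, 80 arms, 17 loci), and counts under the main one by over 1.5 times also without replicate 2 (18 genes, 15 miRNA genes, 19 loci), replicate 3 (12 and 12) and replicate 4 (13, 10 and 19 loci). Every omission leaves the same number of samples, so the smaller number does not account for the differences between omissions. Their cause was not tested. mir-146a, with no call in any of these, ranged from −0.13 to 0.27. Over all alternatives, results for named genes had the same direction and side of the threshold in 365 cases, were weaker in 60 and stronger in 3, and turned direction in 7; for arms 179 were the same and 16 weaker, for loci 177 and 13, and for lists 243 were the same, 34 weaker and 11 stronger. Changes of 1.5-fold were recovered in 16.4% of simulated genes and 68.7% of simulated arms, so small changes can be missed; whether depth sets this limit was not tested.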

Other observations

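The paired tests of arms, the arms outside the lists and the test of snoRNAs were chosen after the values were seen, and the p-values of the paired tests were adjusted over 8 differences. Some strands of the same hairpin, or of the same transcript, did not move alike. miR-411-3p rose by 1.73 ± 1.00 log2 units (SD, n = 9) more than its partner miR-411-5p, in 9 of 9 volunteers (exact sign-flip p = 0.0039, adjusted p = 0.0104). However, miR-411-3p had only 8.27 ± 4.65 scaled reads in control tissue, close to the filter of 5 reads, and 37.9 ± 17.6 in prewound tissue. miR-503, which is cut from the same primary transcript as miR-424, rose by 1.40 ± 0.69 more than miR-424-5p, also in 9 of 9 (exact sign-flip p = 0.0039, adjusted p = 0.0104). The differences between strands were within the spread for miR-21-3p minus miR-21-5p (0.59 ± 1.00, exact sign-flip p = 0.0977), miR-223-5p minus miR-223-3p (−0.98 ± 1.64, exact sign-flip p = 0.117) and miR-142-5p minus miR-142-3p (−0.25 ± 0.55, exact sign-flip p = 0.227). miR-223-3p rose by 1.57 ± 1.99 more than the red cell arm miR-451a (exact sign-flip p = 0.0313, adjusted p = 0.0625).

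Of the 123 arms past the threshold, 48 stood in none of the lists. Among the higher ones were miR-2355-5p (3.03-fold), miR-135b-5p (1.04 ± 0.24), miR-185-5p (0.71 ± 0.14), miR-92b-3p (0.68 ± 0.15) and miR-301a-3p (0.50 ± 0.11). The chromosome 14 arms miR-496 (1.23 ± 0.32) and miR-1185-1-3p (1.24 ± 0.31) were higher as well, although the list did not hold them. Among the lower ones were miR-149-5p (−0.83 ± 0.14), miR-328 (−0.92 ± 0.23), miR-296-5p (−0.89 ± 0.27), miR-148a-3p (−0.57 ± 0.18), miR-193b-3p (−0.47 ± 0.13) and miR-125a-5p (−0.43 ± 0.13). The lower miR-125b-2-3p (−0.92 ± 0.21) comes from the same primary transcript of chromosome 21 as let-7c and mir-99a. In the miR-15 and miR-16 family, miR-497-5p (−0.75 ± 0.17) and miR-195-5p (−0.68 ± 0.16), which lie in 1 cluster, were lower in 9 of 9 volunteers while miR-503 (1.63 ± 0.21) was higher in 9 of 9.

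Between 101335397 and 101533138 of chromosome 14, 44 miRNA hairpins were tested, of which 4 were higher, 0 lower and 36 had a fold change above 0. The SNORD113 and SNORD114 snoRNAs of the same region had a median of 0.40 over 25 genes, with 20 above 0 and 2 past the threshold (camera p = 0.00122, but p = 0.383 with an estimated correlation).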
